A study of Rattus norvegicus with 10 samples.

How the data were processed

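Cortical RNA from male Sprague-Dawley rats was sequenced in 10 libraries. Per the labels, 5 libraries came from cortex after occlusion of the middle cerebral artery for 2 h and 24 h of reperfusion (MCAO/R, a model of ischaemic stroke with restored blood flow), and 5 came from cortex after sham surgery. The labels give an age of 8 to 9 weeks and a weight of 240 ± 20 g for the rats, TRIzol extraction, 1.5 µg of RNA per library, removal of ribosomal RNA with Ribo-Zero and a directional NEBNext Ultra kit. Replicates are numbered 1 to 5 for MCAO/R and 6 to 10 for sham, as in the labels. The groups share no replicate number, so no pairing was used. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples, part of which may be technical.

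The authors deposited 2 tables of FPKM (fragments scaled to transcript length and to a library total), 1 for mRNA and 1 for long non-coding RNA (lncRNA). The submitters' processing notes name the rat build Rnor_5.0. The aligner, assembler, quantification tool and the fragments that make up the library total are not given in the sources used here. The mRNA table held 364224 rows, of which 26001 carried an Ensembl transcript identifier (called annotated transcripts here) and 338223 carried an assembler's locus and isoform number (assembled transcripts, in 275234 loci). The lncRNA table held 31183 rows in 21955 loci, and 3283 loci had rows in both tables. All lncRNA identifiers were of the assembled kind. Neither table nor the reference table of rat genes used here pairs these identifiers with gene symbols: 0 identifiers matched. For that reason the tests of gene lists fixed before the data were examined, on cell types, inflammation, stress responses and synaptic genes, could not be run. FPKM keeps no read totals, so the depth of each library is unknown, and no interval or detection limit that needs it is given. No 2 libraries held identical values.

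Isoform values of 1 assembled locus in the mRNA table were summed to the locus, and annotated transcripts were used as deposited, which gave 301235 features. Features with a mean of at least 0.5 FPKM over the 10 libraries were tested on log2(FPKM + 1). lncRNA rows with a mean of at least 0.1 FPKM were tested as deposited on log2(FPKM + 0.1). Fold changes are on these scales, which understate the change of low features. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term), two-sided, with Benjamini-Hochberg adjustment within each table and a threshold of 0.05. A change of 1 on the log2 scale is 2-fold.

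Tested on simulated data with the spread of the real libraries and 200 changed features, the mRNA procedure on 25038 features recovered 44% of 2-fold and 83% of 4-fold changes, with 10 false calls among 137. The lncRNA procedure on 20293 rows recovered 1% of 2-fold and 29% of 4-fold changes, with 2 false calls among 32. With no feature changed, both gave 0 calls. The simulated values were drawn independently for each feature, without variation that features share between libraries. The number of changed features was set and not taken from the real libraries. These rates therefore hold for that setting and need not hold for the real libraries.

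Quantities with 1 value per library were compared by two-sided exact permutation tests over the 252 assignments of 10 libraries to groups of 5, whose smallest p is 0.00794, and were adjusted by Benjamini-Hochberg over a family of 21 quantities. Ratios of levels within libraries were tested against 0 by exact sign-flip permutation tests over 1024 sign patterns. A correlation between libraries was computed on values centred by group, with an exact permutation test over the 14400 orders within groups for Pearson's r. The permutation p of Spearman's rho came from 100000 random orders of all 10 libraries, not kept within groups. Shares of features were compared by Fisher's exact test, for which features are not independent replicates. The relative level of a class in a library is the median, over rows above 0 in every library, of the log2 ratio to the row's mean across libraries. The position of a library between the groups is its projection on the line from the sham mean to the MCAO/R mean, both computed without that library.

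The rule for named genes was fixed before the data were examined. It took the 6 features with the largest change in each direction among those past the threshold. Their groups had not to overlap, and their mean had to be at least 1 FPKM (0.5 for lncRNA). For mRNA it also asked for a gene symbol, which no row has. Under the rest of the rule, only the first annotated transcript and the first lncRNA in each direction are printed, by identifier. This is fewer than the rule named, also for lncRNA, for which it allowed any identifier. Alternatives covered the pseudocount, the filter, the scaling between libraries, the variance model, library weights, a rank test, the threshold, the summing of isoforms and the omission of each library. Figures were drawn with matplotlib 3.10.9.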

Results

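The series measured cortical transcripts of rats after transient middle cerebral artery occlusion with reperfusion (MCAO/R) and after sham surgery, with 5 libraries in each group. Its title and design text ask how the mRNA and lncRNA transcriptomes differ after MCAO/R and what their basic expression characteristics are. Levels are the authors' FPKM, which carry no read totals, so the depth of the libraries is unknown. Which fragments the library total was taken over is not given in the sources used here, and sums of FPKM and the balance of higher and lower features depend on it. Annotated transcripts summed to 186710 ± 6050 FPKM in MCAO/R and 156991 ± 16944 in sham libraries (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0278 over 21 quantities). The lncRNA table summed to 55133 ± 12734 and 59728 ± 13172 FPKM, a difference within the spread (exact permutation p = 0.587). A single lncRNA row held 20081 and 22460 FPKM of these sums on average, so they say little about most lncRNA.

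The first comparison asked which mRNA features differed between MCAO/R and sham cortex. Annotated transcripts changed mostly upward after MCAO/R: of 10105 tested, 1802 were higher and 287 lower. At 2-fold or more, 636 annotated transcripts were higher and 101 lower. Assembled loci of the mRNA table were less one-sided, with 1788 of 14933 higher and 1013 lower, a majority that turned under 4 other scalings. Across both kinds, 4890 of 25038 features (19.5%) passed, 3590 higher and 1300 lower, and 8634 had an unadjusted p under 0.05. Among called features the share higher was 86.3% for annotated transcripts and 63.8% for assembled loci (Fisher's exact test, odds ratio 3.56, p = 1.24e-72, features not being independent replicates).

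**Figure D1:**
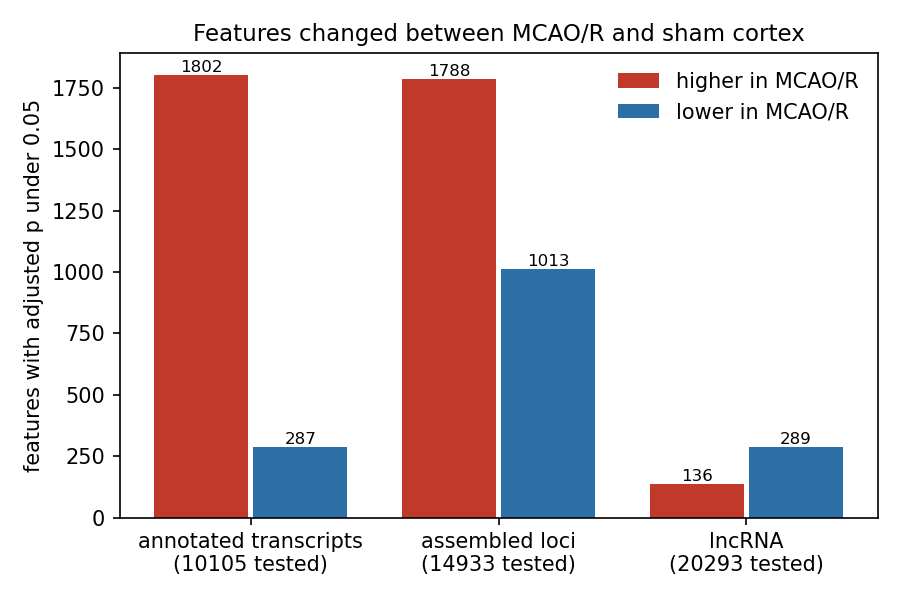
Bars give the number of features with limma adjusted p under 0.05 that were higher (red) or lower (blue) in MCAO/R than in sham cortex, for annotated transcripts, assembled loci of the mRNA table and lncRNA transcripts, with the number tested under each. Annotated transcripts were mostly higher (1802 against 287) and lncRNA mostly lower (136 against 289); with quantile normalization the lncRNA split was 179 higher and 65 lower.

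The annotated transcript with the largest rise, ENSRNOT00000009448, stood at 172 ± 87.0 FPKM in MCAO/R and 0.348 ± 0.239 in sham libraries (SD, n = 5 each). Its log2 fold change was 6.66 with an SE of 0.572 (adjusted p = 0.000131). It was higher in 5 of 5 MCAO/R libraries than in any sham library, as the rule for named genes required, although MCAO/R replicate 3 reached 22.3 FPKM where the next lowest reached 179. The annotated transcript with the largest fall, ENSRNOT00000028546, stood at 7.90 ± 9.82 FPKM in MCAO/R and 34.3 ± 5.82 in sham libraries. It fell by 2.70 on the log2 scale with an SE of 0.685 (adjusted p = 0.0221), and without MCAO/R replicate 5 or sham replicate 9 its adjusted p was 0.0538 or 0.0509. The files do not pair these identifiers with gene names. In 10 annotated transcripts and 7 assembled loci every MCAO/R library had at least 1 FPKM while every sham library was under 0.1. The opposite was found in 0 annotated transcripts and 1 assembled locus.

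**Figure D2:**
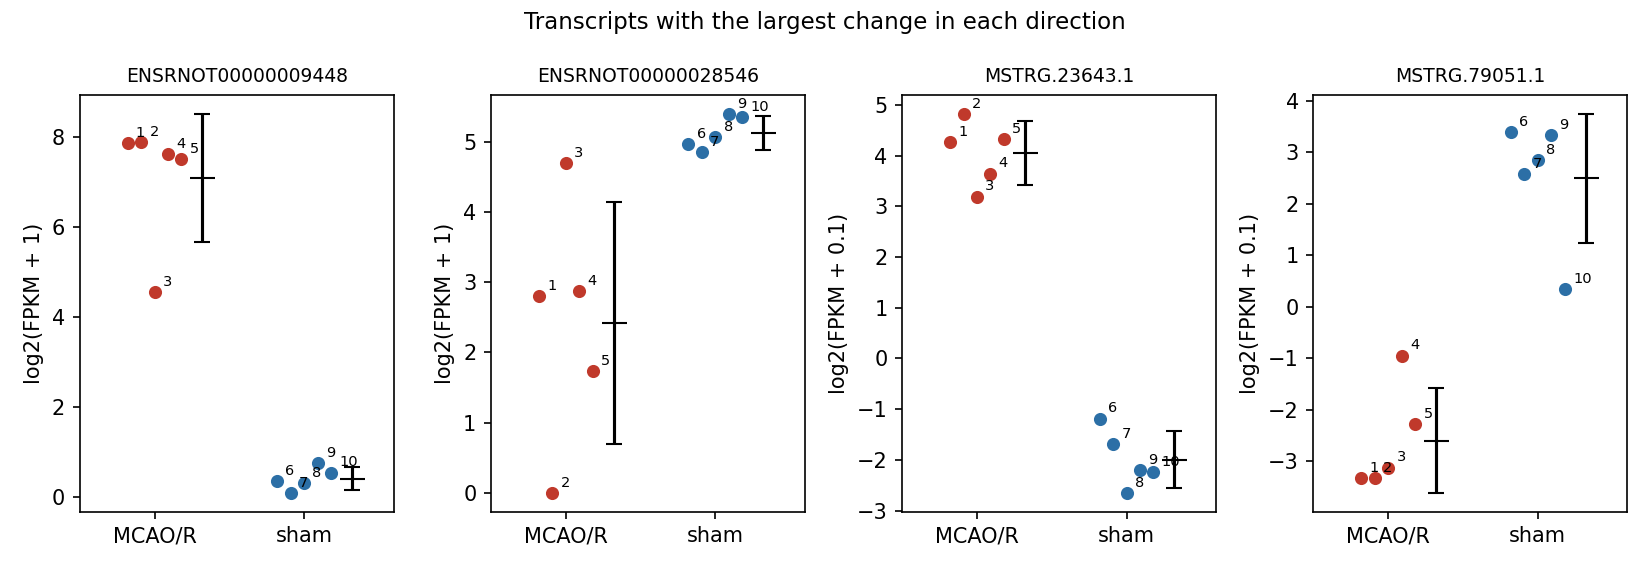
Points give log2 FPKM with the pseudocount of each table, per library and labelled by replicate number, for the annotated and lncRNA transcripts with the largest change in each direction; bars give the mean and SD of 5 libraries. MCAO/R and sham libraries do not overlap for any of the 4 transcripts, which the rule that picked them required. MCAO/R replicate 3 lies nearest to sham for both annotated transcripts.

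The share of annotated transcripts called rose with their level. It was 9.44% of the 1811 transcripts with a mean of 0.5 to 1 FPKM and 37.6% of the 1587 with at least 20 FPKM. Among assembled loci it was 16.3% and 25.7% in the same ranges. The scale of log2(FPKM + 1) understates the change of low features, so this rise does not show that abundant transcripts changed more often. Groups did not overlap for 16.4% of mRNA features, against 0.794% by chance, with 3181 higher and 926 lower in MCAO/R.

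The balance of direction depended on the scaling between libraries, which moved the median log2 fold change of all mRNA features from 0.11 to values between -0.07 and 0.14. Equal sums over both tables also raised every value, which lowered the weight of the pseudocount. Higher and lower features numbered 3590 and 1300 as deposited, 2733 and 1859 with equal sums over both tables, 2482 and 1997 with equal sums without the 20 highest features, 2349 and 2595 with quantile normalization, and 2194 and 2815 with factors from annotated transcripts, an alternative chosen after seeing the data. Under these settings 76.0%, 72.3%, 65.7% and 59.7% of called annotated transcripts were higher, so the majority upward of annotated transcripts held, while that of all features turned under the last 2. Assembled loci numbered 1403 higher and 1438 lower, 1228 and 1516, 1135 and 1960, and 1085 and 2066 under the same 4 settings. The annotated transcripts called lower numbered 481, 635 and 749 without the 20 highest features, with quantile normalization and with factors from annotated transcripts, against 287 as deposited, and 179, 173 and 179 without replicate 1, 5 and 9. Features of both kinds called lower numbered 733, 806, 706 and 714 without replicate 1, 4, 5 and 9, and the total fell to 3226 without MCAO/R replicate 1 and to 3207 without sham replicate 9.

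The second comparison asked which lncRNA transcripts differed. Fewer lncRNA transcripts passed than mRNA features: 425 of 20293 (2.09%). As deposited, 136 were higher and 289 lower in MCAO/R cortex, a split that turned with the scaling and with other settings, and all 425 differed by 2-fold or more. An unadjusted p under 0.05 was reached by 4646. The median log2 fold change over all tested lncRNA was -0.38, and 69.2% of them lay below 0. Groups did not overlap for 274 lncRNA that were higher and 1005 that were lower in MCAO/R, together 6.30% against 0.794% by chance.

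The lncRNA with the largest rise, MSTRG.23643.1, stood at 17.7 ± 7.41 FPKM in MCAO/R and 0.168 ± 0.111 in sham libraries (SD, n = 5 each), a log2 fold change of 6.04 with an SE of 0.353 (adjusted p = 2.59e-06). The lncRNA with the largest fall, MSTRG.79051.1, stood at 0.108 ± 0.179 FPKM in MCAO/R and 6.88 ± 3.71 in sham libraries, and fell by 5.09 on the log2 scale with an SE of 0.591 (adjusted p = 0.00296). Each differed in the same direction in 5 of 5 MCAO/R libraries, as the rule for named genes required, and each value is that of a single assembled isoform.

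The number of changed lncRNA moved with every library. It was 30, 164, 1282, 35 and 16 without MCAO/R replicate 1, 2, 3, 4 and 5, and 893, 12, 28, 24 and 79 without sham replicate 6, 7, 8, 9 and 10. More were higher than lower without MCAO/R replicate 2 (104 and 60), without the intensity trend (76 and 62), on log2(FPKM + 1) (5 and 3) and at an adjusted p under 0.01 (9 and 8), and without MCAO/R replicate 5 there were 8 of each. The split of 136 higher and 289 lower became 193 and 892 with equal sums over both tables, 172 and 935 with equal sums without the 20 highest features, and 179 and 65 with quantile normalization. Factors chosen after seeing the data gave 176 higher and 1411 lower from annotated transcripts and 208 higher and 55 lower from lncRNA rows. The median log2 fold change ran from -0.59 to -0.02 over these settings. The value of -0.59 came with equal sums over both tables, which divided every library by 0.344 to 0.400. That setting therefore also lowered the weight of the pseudocount and is not a change of scaling between libraries alone.

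Within libraries, lncRNA above 0 in every library (9195 rows) stood lower relative to annotated transcripts after MCAO/R than after sham surgery. No scaling of whole libraries alters that comparison, which was not among those fixed before the data were examined. The lncRNA share of the sum of FPKM, which scaling also leaves as it is, overlapped between the groups. It was 14.1 ± 3.1% in MCAO/R and 16.8 ± 3.5% in sham libraries (exact permutation p = 0.246, adjusted p = 0.333). The level of lncRNA relative to annotated transcripts was -0.40 ± 0.19 on the log2 scale in MCAO/R and 0.46 ± 0.45 in sham libraries (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0278). Every MCAO/R library lay below every sham library. Assembled transcripts of the mRNA table shifted the same way, from 0.24 ± 0.23 in sham to -0.18 ± 0.06 in MCAO/R libraries (exact permutation p = 0.00794, adjusted p = 0.0278). The counts of transcripts past a fixed level do depend on the scaling. Annotated transcripts with at least 1 FPKM numbered 7998 ± 88.1 in MCAO/R and 7471 ± 135 in sham libraries (exact permutation p = 0.00794, adjusted p = 0.0278), and their excess of 526 ran from 127 to 1394 under 5 other scalings (exact permutation p up to 0.0238). lncRNA with at least 1 FPKM numbered 1040 ± 147 and 1853 ± 726 (exact permutation p = 0.0159, adjusted p = 0.0417), without MCAO/R replicate 1 or 2 that exact p was 0.0556, and without sham replicate 7 the difference shrank from -813 to -531 transcripts. With factors from lncRNA rows that difference turned to 349 (exact permutation p = 0.0635), while under 4 other scalings it ran from -1438 to -696.

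**Figure D3:**
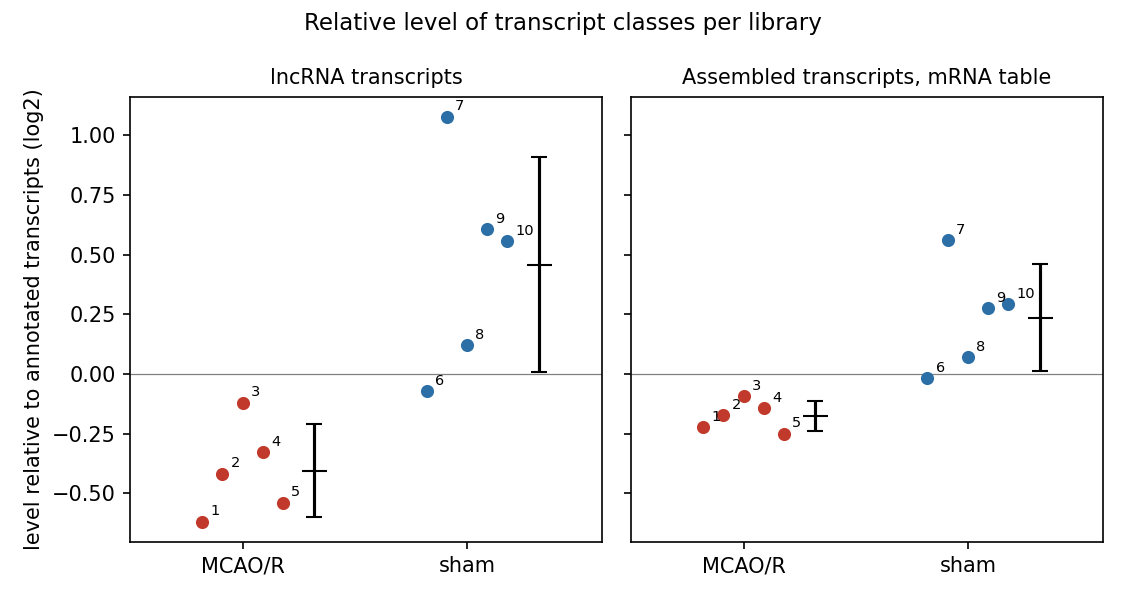
Points give, per library and labelled by replicate number, the level of lncRNA transcripts (left) and of assembled transcripts of the mRNA table (right) relative to annotated transcripts on the log2 scale; bars give the mean and SD of 5 libraries. All MCAO/R libraries lie between -0.62 and -0.09 across the panels and below all sham libraries of the same panel, and sham replicate 7 is the highest in each.

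The third comparison set the level of lncRNA against that of mRNA. Among rows above 0, lncRNA transcripts were lower than annotated transcripts in all 10 libraries, but not lower than the mRNA table as a whole. Against annotated rows above 0, an alternative chosen after seeing the data, the median lncRNA was 3.44-fold lower (mean log2 ratio -1.78 ± 0.38, SD, n = 10, exact sign-flip permutation p = 0.00195, the smallest possible). This log2 ratio was -2.07 ± 0.17 in MCAO/R and -1.50 ± 0.31 in sham libraries (exact permutation p = 0.00794). The gap depended on leaving out zeros. Of the 26001 annotated rows 6112 were 0 in every library, against 0 of the 31183 lncRNA rows. A median with zeros therefore sets annotated transcripts, detected or not, against lncRNA that were all above 0 in some library. With zeros included, an alternative chosen after seeing the data, the log2 ratio of the medians was 0.35 ± 0.62 (n = 10, exact sign-flip permutation p = 0.107), with -0.16 ± 0.22 in MCAO/R and 0.87 ± 0.41 in sham libraries (exact permutation p = 0.00794). Against all rows of the mRNA table above 0, most of them assembled transcripts, the log2 ratio was 0.18 ± 0.25, above 0 in 7 of 10 libraries (exact sign-flip permutation p = 0.0488). This comparison was the one fixed before the data were examined. That ratio to the whole mRNA table was 0.00 ± 0.22 in MCAO/R and 0.36 ± 0.11 in sham libraries (exact permutation p = 0.0159). The group difference kept an exact permutation p between 0.00794 and 0.0317 with any 1 library left out. The ratio pooled over both groups no longer differed from 0 past the threshold without replicate 2, 3, 6, 7, 8, 9 or 10 (exact permutation p from 0.0625 to 0.0977, log2 ratio from 0.15 to 0.19).

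The fourth comparison set the share of lncRNA called against that of mRNA features. The share was 2.09% of lncRNA and 19.5% of mRNA features (Fisher's exact test, odds ratio 0.0881). The units are unlike, since lncRNA were tested as single isoforms and assembled loci of the mRNA table as sums of isoforms. With lncRNA rows summed by locus, 1479 of 14944 loci were called. With assembled rows of the mRNA table tested alone as single isoforms, 504 of 32983 were called. Tested together with annotated transcripts, 2591 of 43088 deposited rows were called, of which 1286 were annotated. The number of single isoforms called therefore also depends on which rows are tested together. Part of the contrast may therefore come from the units. With a pseudocount of 0.1 and a mean of at least 0.1 FPKM in both tables the shares were 2.09% and 5.86% (Fisher's exact p = 1.12e-128). Before adjustment 22.9% of lncRNA and 22.1% of mRNA features had a p under 0.05 in that setting. With each table's own pseudocount and adjustment, lncRNA were also called less often than mRNA features of the same level: 4.45% against 14.0% at 0.5 to 1 FPKM (exact p = 1.77e-43) and 11.1% against 16.6% at 1 to 5 FPKM (exact p = 6.84e-06). Before adjustment the order was the opposite in these ranges, with a p under 0.05 for 40.6% of lncRNA against 29.9% of mRNA features at 0.5 to 1 FPKM and 44.4% against 30.6% at 1 to 5 FPKM, so the shares called do not show that lncRNA changed less often. At 5 to 20 FPKM the shares were 4.20% of 143 lncRNA and 23.1% of mRNA features (exact p = 9.56e-10), and 15.4% and 38.6% before adjustment. At 20 FPKM or more, limma called 0 of 84 lncRNA, 7 of which had an unadjusted p under 0.05, and 32.8% of mRNA features (48.2% before adjustment). With both tables tested on log2(FPKM + 1) and a mean of at least 0.5 FPKM, the shares were 18.4% and 19.5% and no longer differed past the threshold (Fisher's exact p = 0.0957).

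Libraries grouped by surgery. The first principal component of the mRNA features held 33.2% of the variance and separated MCAO/R (11.4 to 67.9) from sham libraries (-58.8 to -41.2). The mean correlation across features, which are not independent replicates, was 0.882 within MCAO/R, 0.903 within sham and 0.841 between the groups. MCAO/R replicate 3 correlated with sham libraries at 0.882 and with its own group at 0.880, while the other MCAO/R libraries correlated with sham at 0.830. MCAO/R libraries lay farther from the mean of the other libraries of their group, at 0.632 ± 0.016 against 0.563 ± 0.027 in sham (root mean square on the log2 scale, n = 5 each, exact permutation p = 0.00794, not adjusted). These distances share libraries and are not independent, so that p is only a guide. The lowest MCAO/R distance was 0.604954 and the highest sham distance 0.604773. MCAO/R replicate 3 stood between the groups for annotated transcripts, at a position of 0.534. The other MCAO/R libraries lay there at 0.811 to 0.924 and sham libraries at 0.103 to 0.255. For lncRNA, MCAO/R replicate 3 lay at 0.466, inside the sham range of 0.027 to 0.503.

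**Figure D4:**
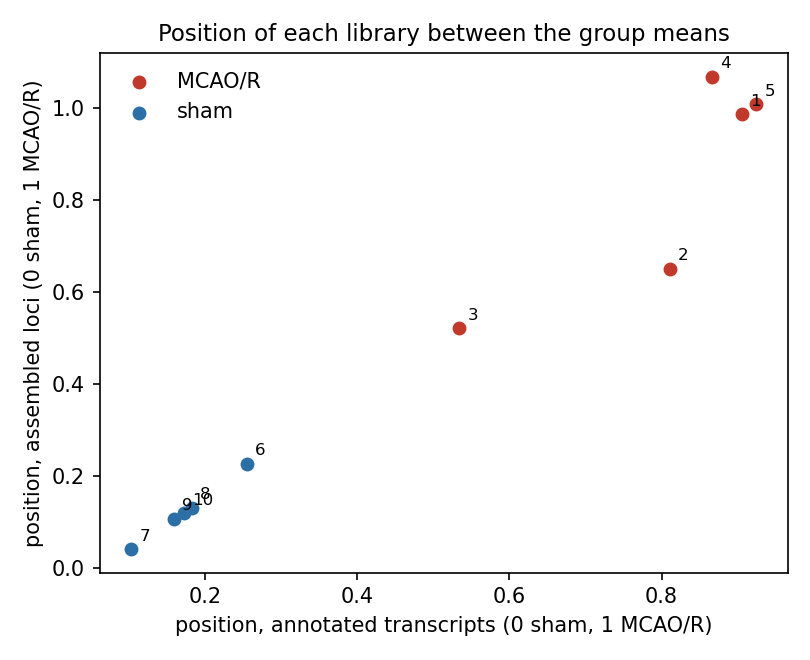
Each point is a library, labelled by replicate number and placed by its position between the sham mean (0) and the MCAO/R mean (1) for annotated transcripts (horizontal) and assembled loci (vertical). MCAO/R replicate 3 lies at 0.534 and 0.521, between the sham libraries and the other MCAO/R libraries on both axes.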

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

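The tests on sham replicate 7, on unannotated RNA and on MCAO/R replicate 3 were chosen after the results were seen; those on other splits of the libraries and on isoforms were fixed before. A single library far from its group was looked for in 58 groups of 5 values, and chance marks about 1 in 20 such groups; 4 were found. ENSRNOT00000009448 was at 22.3 FPKM in MCAO/R replicate 3, where the next lowest MCAO/R library was at 179. ENSRNOT00000028546 was at 24.8 FPKM in MCAO/R replicate 3, where the next highest MCAO/R library was at 6.36. MSTRG.79051.1 was at 0.418 FPKM in MCAO/R replicate 4, with the next MCAO/R library at 0.107. The median level of annotated transcripts was 1.23 FPKM in MCAO/R replicate 5, with the next at 0.991.

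Neither count of changed features was reached by another split drawn. Of 100 splits drawn from those into groups of 5, only 1, the real one, gave 4890 mRNA features, and the highest other split gave 6. Likewise only 1 gave 425 lncRNA transcripts, and the highest other split gave 8. With 100 splits the test cannot exclude chance, and it cannot tell surgery from another difference that follows the groups.

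MCAO/R replicate 3 lay between the groups on mRNA features, and both annotated transcripts named above follow it. Its position of 0.534 for annotated transcripts exceeded the highest sham position, 0.255, by 5.11 SD of the sham positions. On that axis this argues against a sham library under an MCAO/R label. For lncRNA its position of 0.466 lay inside the sham range of 0.027 to 0.503, so that axis does not tell it from sham. In a mixture of sham-like and MCAO/R-like tissue, transcripts that rose and transcripts that fell in the other libraries would be displaced by the same fraction, and the medians were 0.464 over 682 transcripts that rose and 0.431 over 133 that fell, a difference of 0.0332. These medians were 1.17 and 1.01 in replicate 1, 0.742 and 1.11 in replicate 2, 0.960 and 0.924 in replicate 4 and 1.13 and 1.09 in replicate 5, so what sets replicate 3 apart is the size of the fraction and not the match of its 2 medians. A mixture, or a milder injury of the sampled cortex, is a candidate explanation, and the 2 were not separated by any test here.

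In the median over rows above 0 in every library, lncRNA and assembled transcripts were lower relative to annotated transcripts in MCAO/R. Sham replicate 7, the most extreme library, was not the whole cause, since without it the difference was -0.71 on the log2 scale. The exact permutation p without that library, 0.00794, was fixed in advance, because every MCAO/R library lay below every sham library. Inside the groups, libraries with more lncRNA relative to assembled transcripts also had more assembled relative to annotated transcripts (1 relation computed, group-centred Pearson r = 0.935, exact permutation p = 0.000556; Spearman rho = 0.952, permutation p = 9e-05; r = 0.877 without sham replicates 6 and 7). A gradient of unannotated RNA, such as unspliced RNA or background, may therefore run through the libraries, and whether MCAO/R itself or tissue handling sets the group difference was not tested.

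Some abundant rows switched between libraries of 1 group: 47 rows reached 1000 FPKM in a library, and 30 of these did so while under 100 FPKM in another library of the same group. If fragments are shared out between isoforms of 1 locus, its rows would move in opposite directions. The median correlation of the 2 most abundant rows of a locus was -0.177 in 617 loci with group means removed, against -0.00311 for rows of different loci matched on level, a difference of -0.174. Exchange of fragments between isoforms is a candidate explanation, and no biological explanation was tested. An r under -0.5 was found in 31.1% of loci and 9.89% of matched pairs, so single isoform values are less certain than locus sums.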

How the results depend on the processing

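The scalings of the number of transcripts of at least 1 FPKM and the settings that use factors from annotated or lncRNA rows, sum lncRNA rows by locus, use annotated rows only (zeros left out or included) or leave out MCAO/R replicate 3 and sham replicate 7 together were chosen after seeing the data. No called mRNA feature or lncRNA turned sign under any setting in which it was tested. The mRNA count of 4890 stayed within 1.5 times under 21 of 26 settings; it was 1449 with no filter (more features adjusted together), 1623 at an adjusted p under 0.01, 2591 with rows as deposited, and 3207 to 5694 with 1 library left out; without both MCAO/R replicate 3 and sham replicate 7 it was 4599 (lncRNA 428). The lncRNA count of 425 held within 1.5 times under only 2 of 27 settings: 8 and 40 with pseudocounts of 1 and 0.5 (706 with a pseudocount of 1 and a mean of at least 0.5 FPKM together), 262 with no filter, 236 with the filter at 1 FPKM, 244 with quantile normalization, 1085 with equal sums over both tables, 1107 with equal sums without the 20 highest, 138 without trend, 754 with robust eBayes, 847 with array weights, 17 at an adjusted p under 0.01, 12 to 1282 with 1 library left out, 1587 and 263 with factors from annotated and from lncRNA rows, and 1479 with loci summed. The exact rank test gave 0, with 3539 at an unadjusted p under 0.05. Its smallest possible p, 0.00794, became 0.126 after adjustment over the 20293 rows. It could therefore call no lncRNA here, even one whose groups did not overlap. Other causes were not tested.

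The log2 ratio of lncRNA to the mRNA table, 0.18, was 0.14 over rows of at least 0.1 FPKM (exact permutation p = 0.125) and 0.25 as a mean of log2(FPKM + 0.1) (exact permutation p = 0.00195), ran from 0.15 to 0.23 with 1 library left out, turned to -1.78 against annotated rows above 0 and was 0.35 against annotated rows with zeros included (exact permutation p = 0.107). With zeros included the median of the mRNA table was 0 in 10 libraries, so no ratio exists. The difference in lncRNA of at least 1 FPKM, -813, turned to 349 with factors from lncRNA rows. The log2 odds ratio of the shares, -3.50, weakened to -0.11 with pseudocount 1 and a mean of at least 0.5 FPKM in both tables; the other bins and settings kept it past the threshold, and at 20 FPKM or more it was not finite. ENSRNOT00000009448 passed under 26 of 26 settings (adjusted p up to 0.0484) and ENSRNOT00000028546 under 20 (up to 0.0827). MSTRG.23643.1 and MSTRG.79051.1 passed under 25 of 26, all but the rank test (adjusted p = 0.126). The rank test gives every feature without overlap the smallest p of its table, so it adds nothing on these picked transcripts. The alternatives for gene lists (camera, fry) were not run, as no identifier has a symbol. Depth is unknown and limits what can be said of low rows. No paired analysis was possible because the groups share no replicate number.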

Other observations

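The tests of both relations between loci were fixed before their comparison with other splits was seen, and the set of 83 mixed splits was taken out after it. The most abundant row of both tables was an lncRNA transcript, at 20081 ± 1686 FPKM in MCAO/R and 22460 ± 5561 in sham libraries (SD, n = 5 each, exact permutation p = 0.5). lncRNA and mRNA-table rows of the same assembled locus had correlated changes: over 2279 loci the correlation of their log2 fold changes was 0.397. A correlation does not tell how many loci changed in the same direction, which was not counted. These correlations are across loci, which are not independent replicates.

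A shared response of both kinds of row to MCAO/R was a hypothesis for that correlation. The real split gave 0.397, above each of 99 other splits of the libraries, which had a median of -0.02 and a highest value of 0.381. Shuffling the loci 1000 times gave at most 0.0890. The highest other split exchanged MCAO/R replicate 3 for sham replicate 6, and so may carry part of the same contrast; over the 83 splits with 2 or 3 MCAO/R libraries in each group the highest was 0.165.

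Loci with consecutive assembler numbers also had correlated changes, with a correlation of 0.407 over 9881 pairs, 0.286 at a number distance of 10, 0.0590 at 100 and 0.00613 at 2000. Shuffled numbers gave at most 0.0371 in 1000 draws. A shared response of neighbours to MCAO/R was tested by other splits, and 2 of 99 gave as high a value, up to 0.436. Both exchanged only MCAO/R replicate 3, which lies between the groups, for a sham library and so keep most of the surgery contrast, and the 83 mixed splits gave at most 0.357. The response to surgery is therefore left open by this test. The median of the other splits was 0.171, so neighbours also varied together between libraries apart from surgery. Whether consecutive numbers mark neighbours on the genome was not tested, since the tables give no coordinates.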
